A study of Arabidopsis thaliana with 6 samples.

How the data were processed

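RNA from aerial tissue of Arabidopsis thaliana seedlings, 3 wild-type and 3 snl1/2/3/4/5 samples, was sequenced, with a directional library kit started from 1.0 µg of total RNA, per the labels' protocols. The groups and replicate numbers come from the sample titles and genotype labels, and the series description calls the replicates biological. Per the submitters' processing notes, cutadapt 1.4, TopHat, HTSeq and edgeR were used with the TAIR10 genome. The versions of the last 3 tools, the role of each tool and the strand setting of the counting are not given in the sources used here. Where a gene overlaps an antisense neighbour the counts may therefore hold reads of both. Among named genes this applies to SNL1, CO, HDT1, SMZ, LUX, LNK2, ABA2, PORB, TT4, HSP101, PAP17 and PYK10.

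The authors deposited whole-number read counts per gene for each library, over 33602 loci with no normalization, and these counts were the input to every test. The authors also deposited tables of higher and lower genes, with counts per library, a log2 fold change, a log2 mean CPM, a p-value and an adjusted p-value. Which edgeR test gave those p-values is not given in the sources used here. The mutant columns of these tables name the group and not which sample, so they were used by group only, and 12 further columns of CPM per library were not used. The counts in the deposited tables equalled those of the per-library files exactly in 2350 of 2350 gene and group combinations. The ratio of adjusted to unadjusted p of the first gene of the authors' deposited table of lower genes implied 18982 tested genes.

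Gene symbols, classes and neighbours come from the RefSeq annotation of TAIR10.1, which matched 32835 of the 33602 loci by locus tag. Because the notes name TAIR10, no coordinates are printed from it. All 35 loci that the deposited table calls transposable element genes carry the RefSeq class pseudogene. Near-identical copies of named genes were searched with BLAST+ 2.17.0 at 95% identity over 100 bp of exonic sequence. The copies found are given beside the genes in the results, and for SNL6 the search found AT1G10250.

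Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total 15), which left 19591. Scaling used TMM factors, between 0.966 and 1.02, and each gene was tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, group as the single term) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The common dispersion was 0.012. CPM values use the TMM-scaled library totals, the SD is over the 3 libraries of a group, and the standard error of a log2 fold change is its size divided by the square root of the F statistic. Folds are 2 raised to the fitted log2 fold change. For genes with 3 or fewer reads in a group, and for FT and CO, the ratio of summed reads per total count is given with an exact (Clopper-Pearson) 95% interval instead. Such intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

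The 19 gene lists, the rule for naming genes, the tests and most alternatives were written before the data were examined. The lists cover SIN3-like genes, histone deacetylases and partners, flowering promoters, flowering repressors, circadian clock, abscisic acid, ethylene, auxin, seed maturation, salicylic acid defence, jasmonate, photosynthesis, flavonoid and anthocyanin, heat shock proteins, senescence, phosphate starvation, root markers, floral organ markers and shoot meristem markers. 8 list members were left out because no table used here pairs their symbol with the locus. Lists other than the SIN3-like genes were tested with limma 3.58.1 camera (preset correlation of 0.01, log2 CPM with a prior count of 2), with camera on an estimated correlation, and with fry. Named genes were the 6 SNL genes, the 8 highest and 8 lowest log2 fold changes among called genes with at least 1 CPM in the higher group and no overlap between groups, FT, SOC1, CO, FLC and AGL19 in any case, every called flowering gene, deacetylase or partner, and up to 3 called members of each other list by adjusted p. This took 78 genes. Others are said to have been chosen after their values were seen. The values of 1 gene that the rule takes are left out of the text.

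Alternatives changed 1 choice at a time: DESeq2 1.42.0 size factors, library totals alone, no organelle genes, no filter, at least 1 CPM in 3 libraries, limma-voom, a test against 1.5-fold, a replicate block, and each library left out. An exception was the default DESeq2 run on the 25100 genes with reads, which changed filter, scaling and test together. The DESeq2 test alone (same genes and TMM scaling, no independent filtering), a trend on GC content and gene length and a 2-fold size threshold were added after the data were seen. The fit was tested on simulated counts for 19448 genes with the real means and library sizes of the mutant and wild-type comparison. It recovered 40.3% of 67 genes changed 1.5-fold, 80.6% of 67 changed 2-fold and 95.5% of 66 changed 4-fold, and 12 of 156 calls (7.69%) were unchanged genes. The changed genes were a far smaller share than the 34.8% called in the real data, so these rates need not hold there. A simulated changed list was called by camera with either correlation and by fry, and fry also called 1 of 17 unchanged lists. Genes in the simulated lists were independent, while estimated correlations in the real lists reached 0.698. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom of 3.71 to 14.5, so none was treated as a duplicate. With 3 libraries per group, single-value permutation tests cannot go below 0.1.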

Results

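RNA was sequenced from aerial tissue of Arabidopsis thaliana seedlings, 11 days old, in 2 groups of 3 biological replicates. The groups were wild type (ecotype Col-0) and a line with mutations in 5 SIN3-LIKE genes (SNL1 to SNL5), written snl1/2/3/4/5. SNL proteins are plant relatives of yeast Sin3, the scaffold of a histone deacetylase complex that represses transcription. All plants grew in long days of 16 h light and 8 h dark and were harvested 5 h after lights on (ZT5). Total counts were 15194748, 14879617 and 13064598 for wild-type replicates 1 to 3, and 12622416, 15774357 and 13548762 for mutant replicates 1 to 3. The title of the series places the comparison in the question of how SNL genes act on the floral transition in long and short days. Only long-day seedlings were analysed here.

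Transcripts of all 5 mutated genes were lower in the mutant. SNL2 on chromosome 5 fell from 98.1 ± 4.90 to 4.18 ± 2.94 CPM (SD, n = 3 per group), a 23.7-fold difference, and SNL3 on chromosome 1 fell from 76.8 ± 2.56 to 3.87 ± 2.76 CPM, 20.2-fold. Over the alternatives their log2 fold changes ranged from −5.29 to −4.3 and from −5.08 to −3.99. SNL4 fell 6.24-fold, SNL1 2.86-fold and SNL5 1.89-fold. The mutant group thus retained 35.0% of the wild-type level for SNL1, 16.1% for SNL4 and 52.9% for SNL5. Counts per gene do not tell whole transcripts from parts that a mutated gene can leave, so these shares do not measure intact transcript. The adjusted p of these 5 genes lay between 0.000171 and 0.000213 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment), and every mutant library was below every wild-type library. SNL6, which the genotype does not name, had 35.7 ± 2.23 CPM in wild type and 36.7 ± 2.94 CPM in the mutant (log2 fold change 0.04 ± 0.09 SE, adjusted p = 0.753). Mutant replicate 3 stood above replicates 1 and 2 for SNL2 (7.72% of the wild-type mean against 2.37% and 2.7%), SNL3 (9.16% against 3.33% and 2.62%), SNL4 (23.2% against 13.4% and 11.7%) and SNL1 (41.9% against 32.9% and 30.2%).

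**Figure D1:**
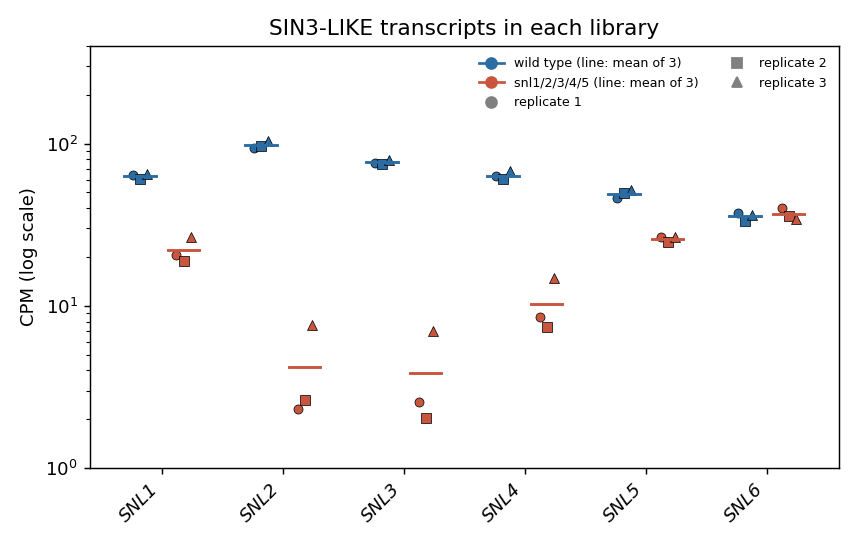
CPM (log scale) of SNL1 to SNL6 in each of the 6 libraries, with wild type in blue, snl1/2/3/4/5 in red, 1 symbol per replicate and a line at each group mean. For SNL1 to SNL5 the 3 mutant libraries lie below the 3 wild-type libraries, and SNL6 overlaps at means of 35.7 and 36.7 CPM.

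Of 19591 genes tested, 3587 were higher and 3224 lower in snl1/2/3/4/5 at an adjusted p below 0.05, together 34.8% of the tested genes. Most changes were small, with a median of 1.46-fold among called genes. At least 2-fold changes were seen in 769 higher and 480 lower genes, and at least 4-fold changes in 114 higher and 87 lower genes. Asked instead for a change significantly above 1.5-fold, the test kept 528 higher and 229 lower genes. Leaving out wild-type replicate 1 gave 2290 higher and 1757 lower genes, and leaving out mutant replicate 2 gave 2486 higher and 1893 lower genes.

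Among the genes with the highest and lowest fold changes were several that the authors' deposited table describes as transposable element genes. AT1G36630, described there as a CACTA-like transposase gene, rose 42.7-fold from 0.254 ± 0.0230 to 11.3 ± 1.10 CPM (adjusted p = 1.37e-05, edgeR quasi-likelihood test). AT4G04293 rose 31.2-fold and AT3G15310 rose 41.6-fold, the last with a near-identical copy at AT5G32621 that makes its reads uncertain. AT1G43590, also listed as a transposable element gene, fell 39.1-fold from 16.2 ± 0.219 to 0.412 ± 0.112 CPM (adjusted p = 1.06e-05), the smallest adjusted p of all genes. The pseudogene AT4G08093 rose 46.1-fold from 4, 1 and 0 wild-type reads, a log2 fold change of 5.53 that ranged from 5.03 to 7.01 over the alternatives (7.01 without wild-type replicate 1). The RefSeq pseudogene AT3G42716 rose from 1 to 52 reads summed over 3 libraries, a ratio of 53.5 with an exact 95% counting interval of 9.18 to 2150.

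The protein-coding gene with the highest fold change was PDF1.3, a plant defensin, with 1 read over the 3 wild-type libraries and 94, 192 and 348 reads in mutant replicates 1 to 3. That is a ratio of 652, with an exact 95% counting interval of 117 to 25800. RTFL18, a member of the ROTUNDIFOLIA-like family of small proteins, rose 22.1-fold to 5.27 ± 1.45 CPM from 2, 8 and 0 wild-type reads, a log2 fold change of 4.47 that ranged from 3.95 to 6.06 (6.06 without wild-type replicate 2). UBC12, a ubiquitin-conjugating enzyme gene, rose from 3 to 60 reads (ratio 20.6, interval 6.71 to 103). Besides SNL2 and SNL3, the lowest fold changes belonged to the F-box gene AT1G78750, with 59 wild-type reads and 1 mutant read (57.4-fold, interval 9.90 to 2300), the pseudogene AT1G34044 (61 against 3 reads), and the ankyrin repeat gene AT3G54070 (53 against 3 reads). The glycosyltransferase gene AT1G05675 fell 39.6-fold and the phloem protein gene PP2-B14 fell 16.1-fold, both from wild-type levels with an SD near the mean (20.5 ± 22.8 and 10.7 ± 10.3 CPM). Over the alternatives their log2 fold changes ranged from −5.88 to −3.96 and from −4.63 to −2.95. Both lost their call without mutant replicate 2 (adjusted p = 0.0731 and 0.071) and with limma-voom (0.273 and 0.119), where their alternatives ranged from 0.00043 to 0.273 and from 0.000761 to 0.119 (the 1.5-fold test, at 0.0797 and 0.0801, included). PP2-B14 also shares sequence with AT1G56242.

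Flowering genes changed in both directions. SOC1, a MADS-box gene that promotes flowering, fell 3.93-fold, from 31.5 ± 2.15 to 8.02 ± 3.44 CPM (n = 3, adjusted p = 0.000862, edgeR quasi-likelihood test). The related MADS-box promoters AGL24 and AGL42 rose 2.77-fold (adjusted p = 0.00034) and 3.25-fold (0.0015). Among repressors, MAF5 rose 4.53-fold to 10.2 ± 0.605 CPM, ATC, a relative of TERMINAL FLOWER 1, rose 6.70-fold to 8.29 ± 2.32 CPM, and the AP2-like genes SMZ, TOE1 and TOE2 rose 2.07-, 1.4- and 1.47-fold. MAF4 rose 1.67-fold, while its neighbour MAF3 fell 1.3-fold and the RAV-type repressors TEM1 and TEM2 fell 1.36- and 1.32-fold.

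Of 10 tested flowering promoters, 2 rose, 1 fell and 7 did not pass the test, with the same counts when adjusted over the list alone. Over all tested genes 18.3% were higher and 16.5% lower, so the promoter counts are near the average share. The counts of the other lists are to be read against the same shares, and counts near them do not mark a list as affected. Of 19 tested repressors, 6 rose, 3 fell and 10 did not pass, and 7 rose and 5 fell when adjusted over the list alone. Neither list moved one way against other genes (camera adjusted p = 0.833 and 0.848). The median log2 fold change was −0.05 for promoters and −0.15 for repressors, against means of 0.10 and 0.23 and a camera direction of up. FLC, the central repressor in the vernalization pathway, had 3.79 ± 0.788 CPM in wild type and 2.46 ± 0.376 CPM in the mutant (log2 fold change −0.63 ± 0.22 SE, adjusted p = 0.0518). It passed the threshold in 5 alternatives: scaling by library totals (0.049), no organelle genes (0.0491), the trend on GC content and length (0.0478), and without wild-type replicate 3 (0.031) or mutant replicate 3 (0.0446). Its range over the alternatives other than the 1.5-fold test was 0.031 to 0.171. AGL19 had 0.784 ± 0.0972 and 1.15 ± 0.602 CPM (adjusted p = 0.334), and passed only without mutant replicate 3 (0.0355, range 0.0355 to 0.65). The MAF4 call was lost without wild-type replicate 1 or 3 or mutant replicate 2 (adjusted p = 0.0726, 0.0556 and 0.0698, range 0.00858 to 0.0726). The TEM1 call was lost without wild-type replicate 1 or 2 or mutant replicate 1 or 2 (0.121, 0.114, 0.0965 and 0.137, range 0.00354 to 0.137), and the TEM2 call without wild-type replicate 1 or 2 or mutant replicate 2 (0.0762, 0.0711 and 0.0686, range 0.00508 to 0.0762). The call of MAF3 (AT5G65060) was lost with the default DESeq2 run (0.0545, range 0.00438 to 0.0545), which also changes the filter and scaling, and kept with the DESeq2 test alone (0.0482). The TEM1 and TEM2 calls were also lost with a replicate block (0.069 and 0.051). Without mutant replicate 1, 3 promoters rose and 2 fell. The 3 lower repressors became 1 without wild-type replicate 1 or 2 or mutant replicate 2 and with the replicate block, 5 without mutant replicate 3, and 6 after correction for GC content and length.

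FT and CO were too low to enter the test. FT, the long-day florigen gene, had 1, 0 and 0 reads in wild type and 4, 13 and 5 reads in the mutant, a ratio of 22.6 with an exact 95% counting interval of 3.66 to 934. CO, which activates FT in long days, had 8, 12 and 7 reads in wild type and 5, 3 and 5 in the mutant, a ratio of 0.495 (interval 0.235 to 0.993), and an antisense neighbour, AT5G15845, overlaps it. For each gene a 2-sided exact permutation test on the 6 CPM values gave p = 0.1, the smallest p that 3 against 3 libraries allow. In the fit without a filter on low counts, the adjusted p was 0.01 for FT and 0.145 for CO.

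**Figure D2:**
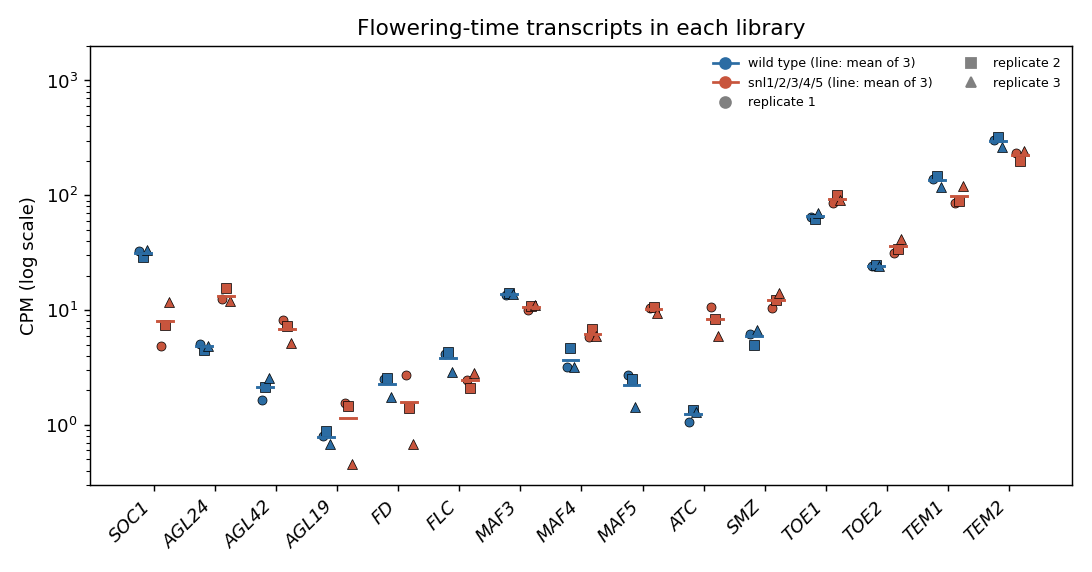
CPM (log scale) of 15 flowering-time genes in each of the 6 libraries, with wild type in blue, snl1/2/3/4/5 in red, 1 symbol per replicate and a line at each group mean. SOC1 lies lower in the mutant (8.02 against 31.5 CPM), and AGL24, AGL42, MAF5, ATC and SMZ lie higher in all 3 mutant libraries.

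Among 12 tested histone deacetylases and partners, HDT3 rose 1.2-fold, HDA5, HDA15 and HDT1 fell 1.35-, 1.31- and 1.28-fold, and 8 did not pass, with the same counts when adjusted over the list alone. HDA19, a deacetylase that works with Sin3-type proteins, named after its values were seen, had 95.1 ± 4.29 and 101 ± 5.48 CPM (adjusted p = 0.387, edgeR quasi-likelihood test). The list's median log2 fold change was 0.02, its mean −0.04 and its camera direction down (adjusted p = 0.833). Leaving out wild-type replicate 1 or 2 ended the HDT1 call (0.0635 and 0.0596, range 0.0139 to 0.0635), and leaving out wild-type replicate 1 or 3 or mutant replicate 2 ended the HDT3 call (0.0663, 0.0629 and 0.0541, range 0.0149 to 0.0663). HDA15 shares sequence with AT4G09784. In the circadian clock list, 3 of 21 genes rose, 5 fell and 13 did not pass, and 4 rose and 5 fell when adjusted over the list alone (camera adjusted p = 0.958). The evening complex gene LUX rose 1.80-fold, and the morning-phased genes LNK2 and RVE4 fell 1.56- and 1.41-fold. Named after their values were seen, the other changed clock genes were ELF4 and PRR3 (2.3- and 1.66-fold up) and ZTL, PRR7 and LKP2 (1.31-, 1.34- and 1.27-fold down). The PRR3 call was lost without wild-type replicate 1 or 2 or mutant replicate 1 (0.108, 0.0867 and 0.0793), with the DESeq2 test alone (0.0548) or in its default run (0.0652) and with a replicate block (0.0535, range 0.0304 to 0.108). The LKP2 call was lost without wild-type replicate 1 or mutant replicate 2 (0.0633 and 0.0554, range 0.0123 to 0.0633). After correction for GC content and length, 6 clock genes rose.

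Among jasmonate genes, 8 of 18 tested rose, 1 fell and 9 did not pass, with the same counts when adjusted over the list alone. Besides PDF1.3, the biosynthesis genes AOC2 and AOS rose 2.16- and 1.54-fold, to 51.9 ± 16.4 and 139 ± 17.1 CPM (SD of 3 libraries). The gene that fell was LOX4, a lipoxygenase (7.12-fold), whose 3 wild-type libraries had 13.2, 2.49 and 39.2 CPM. Its call was lost without wild-type replicate 1 or 3 or mutant replicate 1 or 2 (adjusted p = 0.0681, 0.119, 0.0949 and 0.124) and with limma-voom (0.204, range 0.00628 to 0.204). The 8 higher jasmonate genes became 5 without wild-type replicate 1 or 2 and 4 without mutant replicate 2. The 1 lower gene became 0 without wild-type replicate 1 or 3 or mutant replicate 1, 2 without wild-type replicate 2 and 4 without mutant replicate 3. The list's camera adjusted p was 0.458, from the smallest unadjusted p of the lists, 0.03. In the salicylic acid defence list, 1 of 11 rose, 4 fell and 6 did not pass, again the same when adjusted over the list alone (camera adjusted p = 0.458). In the fit without a filter on low counts, 20 members entered, of which 2 rose and 4 fell. PR2, named after its values were seen, was under the filter, with 0 wild-type reads and 8, 13 and 1 mutant reads. Its adjusted p in the edgeR fit without a filter was 0.0197, and its 2-sided exact permutation p was 0.1. The transcription factor gene WRKY70 fell 3.18-fold, from 37.9 to 12 CPM, and PAD4, a regulator of salicylic acid accumulation, fell 1.64-fold, while the pathogenesis-related gene PR5 rose 4.28-fold to 2.12 ± 0.788 CPM. SARD1 and NPR1, a regulator of systemic resistance, fell 3.09- and 1.3-fold. The 4 lower genes of this list became 2 without wild-type replicate 1 or 3 or mutant replicate 2, and 7 without wild-type replicate 2. Lost calls were SARD1 without wild-type replicate 1 or 3 or mutant replicate 1 or 2 (adjusted p = 0.0944, 0.124, 0.0941 and 0.143) and with limma-voom (0.0842, range 0.0094 to 0.143), and NPR1 without wild-type replicate 1 or 3 or mutant replicate 2 (0.0502, 0.0617 and 0.0885, range 0.0189 to 0.0885).

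In the abscisic acid list, 1 of 17 rose, 4 fell and 12 did not pass, the same when adjusted over the list alone (camera adjusted p = 0.458). CYP707A3 and CYP707A2, which encode enzymes that degrade abscisic acid, fell 3.0- and 2.76-fold, and ABA2, a biosynthesis gene, rose 1.47-fold. CYP707A3 had 7.04, 5.35 and 16.75 CPM in mutant replicates 1 to 3, and its log2 fold change of −1.58 ranged from −2.23 to −1.27 over the alternatives. The others that fell were RD29B (2.59-fold) and NCED3, which encodes an enzyme of abscisic acid synthesis (2.91-fold), the last with 22.0, 10.2 and 44.2 CPM in the 3 wild-type libraries. The NCED3 call was lost without any 1 library other than wild-type replicate 2 (adjusted p = 0.0605 and 0.0538 for wild-type replicates 1 and 3, and 0.0636, 0.0901 and 0.0599 for mutant replicates 1 to 3) and with limma-voom (0.0859, range 0.00373 to 0.0901). Without mutant replicate 1, 2 abscisic acid genes rose. Of 11 ethylene genes, 2 rose, 0 fell and 9 did not pass (camera adjusted p = 0.612), with ACO4, encoding an ethylene-forming enzyme, up 1.42-fold. Of 20 auxin genes, 5 rose, 0 fell and 15 did not pass (camera adjusted p = 0.458), with IAA17 up 1.85-fold, IAA7 up 1.46-fold, the biosynthesis gene YUC8 up 2.1-fold, IAA29 up 1.97-fold and the auxin efflux carrier gene PIN7 up 1.28-fold. Both lists gave the same counts when adjusted over the list alone. Without mutant replicate 3, 3 ethylene genes rose and 1 fell. The 5 higher auxin genes became 3 without wild-type replicate 1, 2 or 3 or mutant replicate 2, and without mutant replicate 1 there were 4 higher and 2 lower. The IAA29 call was lost without wild-type replicate 1, 2 or 3 or mutant replicate 2 (adjusted p = 0.0661, 0.0765, 0.078 and 0.0613, range 0.0022 to 0.078). The PIN7 call was lost without any 1 library other than mutant replicate 3 (0.0569, 0.098 and 0.118 for wild type, 0.0908 and 0.104 for the mutant) and when scaled by library totals (0.0524, range 0.00788 to 0.118). LOX4, SARD1, NPR1, RD29B, NCED3, IAA29 and PIN7 were named after their values were seen.

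Among other pathways, 20 of 23 photosynthesis genes did not pass the test (camera adjusted p = 0.75). In that list RBCS1B rose 1.79-fold, PORB rose 1.39-fold and CAB2 fell 1.27-fold. CAB2 shares near-identical sequence with AT1G29930. The CAB2 call was lost without any 1 of the wild-type replicates or without mutant replicate 2, and the PORB call without any 1 library other than mutant replicate 3. Their adjusted p without 1 library reached 0.15 and 0.133, both without wild-type replicate 1 (ranges over the alternatives 0.00259 to 0.15 and 0.000915 to 0.133). A replicate block also ended both calls (0.109 and 0.0714), and limma-voom (0.0532) and scaling by library totals (0.0542) ended that of PORB. Without mutant replicate 3, 3 photosynthesis genes fell. Adjusted over the list alone, 1 rose and 0 fell, and the list's median log2 fold change of −0.0033 and its downward camera direction stood against a mean of 0.0126. Of 10 flavonoid and anthocyanin genes, 4 rose, 1 fell and 5 did not pass (camera adjusted p = 0.612), with the early pathway genes TT4, FLS1 and TT5 up 1.97-, 2.53- and 1.82-fold, UGT78D2 up 1.3-fold and the repressor gene MYBL2 down 1.34-fold. Of 7 heat shock genes, 3 rose, 2 fell and 2 did not pass (camera adjusted p = 0.606), and HSP101, HSP90.1 and HSP70 rose 2.95-, 1.91- and 2.06-fold while HSP17.4 and HSA32 fell 2.55- and 1.49-fold. Of 8 senescence genes, 1 rose, 3 fell and 4 did not pass (camera adjusted p = 0.458). The senescence regulator NAP fell 3.58-fold (59.7, 37.8 and 84.4 CPM in the 3 wild-type libraries), SEN1 fell 1.66-fold and WRKY53 fell 7.41-fold (29.1, 6.74 and 55.6 CPM). Like LOX4, NCED3, AT1G05675 and PP2-B14, NAP and WRKY53 were highest in wild-type replicate 3 and lowest in replicate 2, so these falls may not be separate results. The salicylic acid list as a whole may share this variation, with 3079, 2285 and 3190 summed reads in wild-type replicates 1 to 3. SAG29 rose 5.45-fold to 2.77 ± 1.80 CPM, a log2 fold change of 2.45 that ranged from 1.74 to 2.92 over the alternatives. Of 8 phosphate starvation genes, 3 rose, 1 fell and 4 did not pass (camera adjusted p = 0.458), with the acid phosphatase PAP17 up 1.91-fold, SPX1 up 1.7-fold, SQD1 up 1.24-fold and the galactolipid synthase MGD2 down 3.19-fold. The SPX1 call was lost without mutant replicate 2 (adjusted p = 0.0564, range 0.00333 to 0.0564). UGT78D2, MYBL2, HSP17.4, HSA32, WRKY53 and SQD1 were named after their values were seen. Each of these 6 calls was lost without at least 1 of the libraries. Fits without 1 library kept only 58.7% (without wild-type replicate 1) to 89.3% (without mutant replicate 3) of all calls. A call lost in such a fit therefore need not rest on the library left out. UGT78D2 was lost without any 1 library other than mutant replicate 1 (adjusted p = 0.09, 0.138 and 0.0906 for wild type, 0.079 and 0.0901 for the mutant), with the DESeq2 test alone (0.055) or in its default run (0.0647), with limma-voom (0.0527) and with a replicate block (0.0538, range 0.0251 to 0.138). MYBL2 was lost without wild-type replicate 1 or mutant replicate 2 (0.061 and 0.0604, range 0.00229 to 0.061), which left 0 lower flavonoid genes. Of the lower heat shock genes, HSP17.4 was lost without wild-type replicate 1 or 2 or mutant replicate 1 or 2 (0.0783, 0.0924, 0.0639 and 0.106) and with a replicate block (0.0638, range 0.0145 to 0.106). HSA32 was lost in the same 5 cases (0.114, 0.0899, 0.073, 0.127 and 0.0518) and without wild-type replicate 3 (0.0538, range 0.00244 to 0.127), so that in those 5 cases 0 heat shock genes fell. WRKY53 was lost without mutant replicate 2 (0.066) and with limma-voom (0.0829, range 0.00195 to 0.0829). SQD1 was lost without wild-type replicate 1 or 3 or mutant replicate 2 (0.0627, 0.0889 and 0.0933, range 0.0225 to 0.0933), and without mutant replicate 2 only 1 phosphate starvation gene rose. Adjusted over the list alone, the counts were 4 and 1 for flavonoid genes, 4 and 2 for heat shock, 1 and 3 for senescence and 3 and 1 for phosphate starvation (higher and lower).

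Markers of other organs were examined to ask whether the samples, labelled as aerial tissue, held root, floral or meristem transcripts. PI, a petal and stamen identity gene, rose 6.29-fold, from 2.80 ± 0.757 to 17.5 ± 6.53 CPM, 0 of the 3 tested floral organ genes fell, and SEP3 and SEP4 did not pass (camera adjusted p = 0.475). Most floral organ genes were under the filter. In the fit without a filter on low counts, 11 members entered and the list stood higher (camera adjusted p = 0.0104, adjusted p = 0.522 with an estimated correlation, range over the alternatives 0.0104 to 0.93). The reads over 3 libraries were 5 and 27 for AP3, 4 and 14 for AG and 3 and 22 for SEP1 in wild type and mutant, with ratios of 5.55 (exact 95% counting interval 2.11 to 18.5), 3.60 (1.13 to 15) and 7.54 (2.27 to 39.4). In the fit without a filter their adjusted p was 0.0128, 0.15 and 0.0269, so AG did not pass, and the 2-sided exact permutation p was 0.1 for each. These 3 genes were chosen after their values were seen. Of 6 shoot meristem genes, 2 rose, 1 fell and 3 did not pass (camera adjusted p = 0.458): KNAT1 rose 1.7-fold, KNAT6 rose 1.38-fold and CLV1 fell 1.25-fold. The KNAT6 call was lost without any 1 library other than wild-type replicate 3 or mutant replicate 2, and the CLV1 call without wild-type replicate 1 or 3 or mutant replicate 2. Their adjusted p reached 0.146 and 0.0888, both without wild-type replicate 1 (ranges 0.0425 to 0.146 and 0.0114 to 0.0888). The KNAT6 call was also lost with the DESeq2 test alone (0.0649) or in its default run (0.0759), limma-voom (0.0538), library totals (0.059) and a replicate block (0.0639), and both calls after correction for GC content and length (0.0587 and 0.0535). Of 12 root markers, 3 rose, 0 fell and 9 did not pass (camera adjusted p = 0.606). PYK10, a beta-glucosidase gene of endoplasmic reticulum bodies, rose 2.39-fold, from 1134 ± 27.6 to 2706 ± 410 CPM, the iron transporter IRT1 rose 1.86-fold and the aquaporin TIP2;3 rose 1.66-fold. Without mutant replicate 1, 2 root markers fell, and 2 floral organ genes rose without wild-type replicate 1, 2 or 3 or mutant replicate 2. The root hair gene EXPA7 had 5.25 ± 0.588 and 5.94 ± 0.645 CPM (adjusted p = 0.378), and the endodermal gene CASP1 had 23.2 ± 1.86 and 26.5 ± 3.69 CPM (adjusted p = 0.231). Root marker transcripts were thus present in both groups although the labels name aerial tissue. Whether root tissue was carried into the samples was not tested, so changes of such genes cannot be assigned to the shoot. For the floral, meristem and root lists the counts were the same when adjusted over the list alone. SEP3, SEP4, EXPA7 and CASP1 were named after their values were seen. No seed maturation gene entered the test, and its 17 members had 55 wild-type and 97 mutant reads in all.

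**Figure D3:**
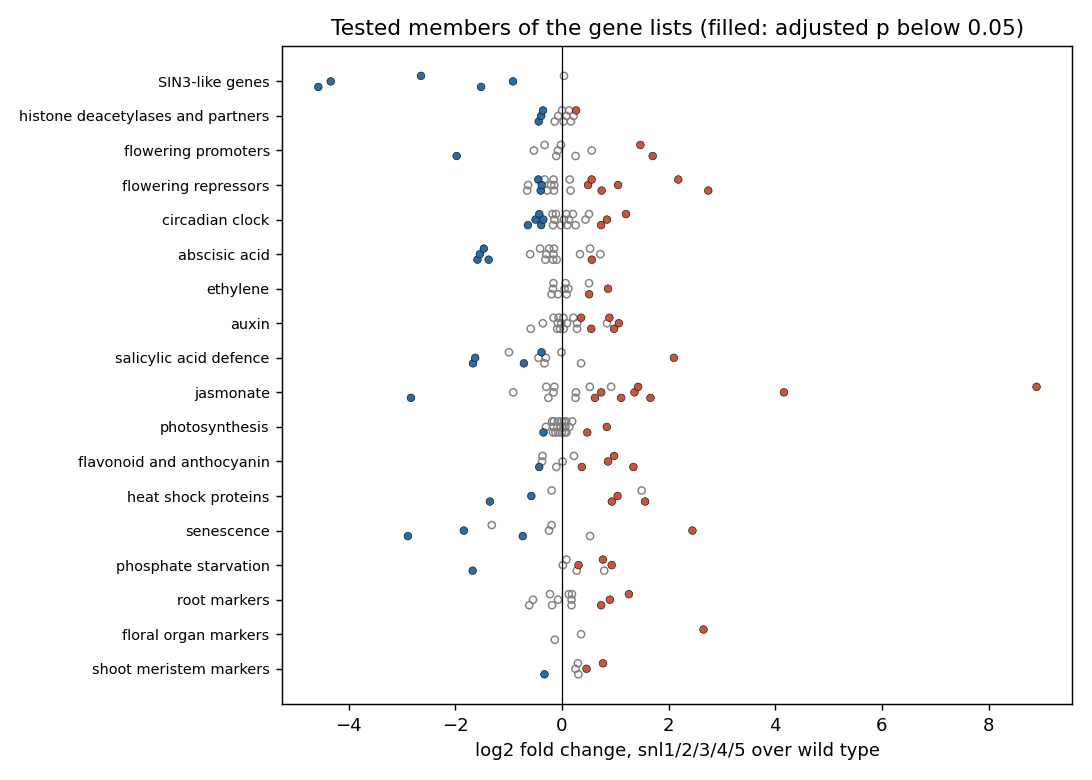
Log2 fold change (snl1/2/3/4/5 over wild type) of every tested member of the gene lists, 1 point per gene. Filled points passed an adjusted p of 0.05 (red higher, blue lower) and open grey points did not. The 5 mutated SNL genes lie to the left, most photosynthesis genes lie near 0, and the point on the far right is PDF1.3, with a fitted log2 fold change of 8.90 against 1 wild-type read.

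Of the 17 gene lists tested, 0 passed an adjusted p of 0.05 with camera, 1 had an unadjusted p below 0.05, and with an estimated correlation 0 passed either limit. With limma-voom 0 passed and 2 had an unadjusted p below 0.05. The fry test for movement in one direction also passed 0 (smallest adjusted p = 0.0864, 6 lists with an unadjusted p below 0.05), and its test for change in either direction, which compares a list with no other genes, passed all 17.

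The authors' deposited table holds 695 higher and 480 lower genes, with the lowest absolute LogFC at 1.0. All of these were tested here and 0 had the opposite sign, and 686 of the higher (98.7%) and 451 of the lower ones (94.0%) passed an adjusted p of 0.05. In the other direction, 686 of 769 higher and 439 of 480 lower genes called here at 2-fold or more were in the deposited table. Both analyses used the same counts, so the shared signs are not independent support. Across genes, the level in wild-type replicate 1 was weakly and negatively related to the log2 fold change of the mutant against wild-type replicates 2 and 3 (Spearman's rho −0.127, with −0.104 and −0.148 when replicates 2 and 3 served as the baseline). Genes are not independent replicates, so no p is attached. Among genes binned by mean level over the 6 libraries, higher genes made up 57.2% of calls in the lowest of 5 bins and 50% in the highest, and 58.2% and 66.7% of calls of at least 2-fold. With genes binned by wild-type replicate 1 and calls from the fit without it, these shares were 71% and 47.3% of all calls and 69.2% and 53.5% of calls of at least 2-fold. Both divisions were chosen after the data were seen, and the trend at 2-fold depended on the division. A gene with few wild-type reads could enter the test through high mutant counts, while a gene low in both groups could not. The filter can therefore make part of any trend with the wild-type level, rho included, and no conclusion is drawn from it.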

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

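The DESeq2 test alone, the GC and length trend and the 2-fold size threshold were added after the data were seen. The 5 mutated SNL genes stayed lower and past the threshold in all 17 alternatives. The counts of 3587 higher and 3224 lower genes fell to 528 and 229 with the test against 1.5-fold and to 769 and 480 with the 2-fold threshold, since both ask for larger changes. Leaving out 1 library gave 2290 to 3806 higher and 1757 to 3511 lower genes. The lowest counts came without wild-type replicate 1, and 1893 lower genes were left without mutant replicate 2. The other alternatives kept both counts within 1.5 times. No scaling moved the median log2 fold change of all genes by 0.1. Flowering promoters stayed short of the threshold in all 15 alternatives (adjusted p 0.289 to 0.962, leave-outs 0.621 to 0.962). Flowering repressors also did (0.0864 to 0.934, leave-outs 0.736 to 0.932), with the direction reversed without mutant replicate 3 (adjusted p = 0.928). The cause was not tested. The number of lists past the threshold was 0 in 14 of 15 alternatives and 1 without a filter on low counts, where 11 floral organ genes entered in place of 3 (adjusted p = 0.0104, and 0.522 with an estimated correlation). At an adjusted p of 0.01, 556 of the higher and 300 of the lower genes of the authors' deposited table passed here. The baseline correlation of −0.127 moved to −0.104 with wild-type replicate 2 as the baseline, and the cause was not tested.

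Over 76 tested named genes, 1186 of 1287 alternative values kept their direction and side of the threshold, 93 lost the call (43 of them in the test against 1.5-fold and 34 when 1 library was left out), 6 gained it and 2 reversed. A further 5 had no value, being under a stricter filter. Both reversals were SNL6 (AT1G10450), at log2 fold changes of −0.012 without wild-type replicate 2 and −0.0249 without mutant replicate 1, where leaving out 1 library gave −0.0249 to 0.0841. The replicate numbers gave no clear pairing of the samples: deviations from the group means correlated at 0.014, 0.15 and −0.056 for replicates of the same number. The 0.15, for replicates 2, was the largest of all, followed by 0.13 for mutant replicate 1 and wild-type replicate 3. A weak pairing is not excluded. A fit with a replicate block gave 3106 higher and 2768 lower genes. FT, CO, most floral organ genes and the seed maturation list had too few reads for the test. All libraries share the same age, harvest time and tissue. Whether these or the sequencing depth kept the reads low was therefore not tested.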

Other observations

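The family enrichments, both tests on mutant replicate 3 and the genes named here were chosen after the data were seen. The 311 families of at least 10 tested genes were taken from RefSeq product names, symbol stems and gene classes and set against all tested genes (Fisher's exact test, 2-sided, Benjamini-Hochberg over 622 tests, 23 past 0.05, of which 5 were depletions), after unclassed and protein-coding genes as a whole had been dropped as families. Genes of the peroxidase superfamily stood first, with 32 of 49 higher, 3 lower and 8.97 expected higher (adjusted p = 3.41e-10), and 20 higher without wild-type replicate 1. The peroxidase gene AT2G37130 rose 4.45-fold, from 121 ± 8.37 to 541 ± 19.1 CPM (SD of 3 libraries). Of 14 fasciclin-like arabinogalactan protein genes 13 were higher and 0 lower (adjusted p = 9.24e-07), with FLA8 up 2.51-fold and FLA15 up 3.5-fold. Of 16 alpha-expansin genes, whose products loosen cell walls, 13 were higher and 0 lower (adjusted p = 1.7e-05), with EXPA10 up 2.25-fold and EXPA4 up 3.6-fold. AGP-named arabinogalactan proteins (16 of 25), pectin lyase-like proteins (23 of 48), GDSL lipases (22 of 44) and lipid-transfer proteins (23 of 49, with 7 lower) followed. The 23 higher pectin lyase-like genes became 12, 13 and 12 without wild-type replicate 1, wild-type replicate 2 and mutant replicate 2. The enrichment tests themselves were not repeated without single libraries. The median log2 fold change of each of these families was above 0 with TMM, with DESeq2 size factors and with library totals. The families were picked for their higher members and the 3 scalings differ little, so this could hardly have come out otherwise. Members of a family can share regulation, so they are not independent genes. Of 12 root markers, 3 also rose (PYK10, IRT1 and TIP2;3) and EXPA7 and CASP1 did not pass, and whether the share of tissues differed was not tested.

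Genes of the histone superfamily were higher in 14 of 27 cases and lower in 1 (Fisher's exact test, adjusted p = 0.00401), with AT1G09200 up 1.86-fold and AT5G59970 up 1.76-fold. The 14 became 6, 9 and 8 without wild-type replicate 1, wild-type replicate 2 and mutant replicate 2. Higher genes were also enriched in the symbol stems SCPL (15 of 29, 4 lower, adjusted p = 0.00251), HSP (11 of 19, 2 lower, 0.00525), PIP (11 of 19, 0 lower, 0.00525), BGLU (13 of 25, 2 lower, 0.00531), GSTU (11 of 22, 0 lower, 0.0227) and BZIP (10 of 19, 0 lower, 0.0227) and among nucleotide-sugar transporters (11 of 19, 2 lower, 0.00525). The PIP stem mixes aquaporin genes with PIP5K kinase genes, and its 11 became 4 and 6 without wild-type replicates 1 and 2. HSP fell to 7 without wild-type replicate 1 or 3, nucleotide-sugar transporters to 7 without wild-type replicate 1, and BZIP to 5, 6 and 5 without wild-type replicate 1, wild-type replicate 3 and mutant replicate 2. Lower genes were enriched for TIR-NBS-LRR disease resistance genes, with 18 of 51 lower and 2 higher (adjusted p = 0.0267), among them RPP5, which fell 1.69-fold from 211 ± 17.3 CPM. These 18 became 12 without wild-type replicate 1 or 3, 8 without mutant replicate 2 and 24 without wild-type replicate 2. The number of lower salicylic acid genes moved the same way, so both may reflect the same variation among wild-type libraries. RNI-like genes were lower in 13 of 32 and higher in 1 (adjusted p = 0.0267), and lower in 6 without wild-type replicate 1 or mutant replicate 2. The default DESeq2 run, which also changes filter and scaling, gave 8 lower RNI-like and 15 higher pectin lyase-like genes, against 9 and 17 with its test alone. The test against 1.5-fold lowered the count of every enriched family by over 1.5 times, to 11 for peroxidases and to 1 each for histones, nucleotide-sugar transporters, PIP, BGLU, BZIP, TIR-NBS-LRR and RNI-like genes. RefSeq pseudogenes, which here include transposable element genes, were lower in 42 of 130 cases and higher in 19, with 21.4 expected lower (adjusted p = 0.00047). Among them SADHU1-3 fell 4.65-fold and MUG8 fell 1.99-fold. Fewer genes than expected were higher among tetratricopeptide repeat (20 of 249, 45.6 expected, adjusted p = 0.00047), pentatricopeptide repeat (11 of 174, 31.9 expected, 0.00047), EMB-named (10 of 157, 28.7 expected, 0.00149) and C1 domain genes (4 of 80, 14.6 expected, 0.0227). Pentatricopeptide repeat genes were also lower in fewer cases than expected (13 of 174, 28.6 expected, 0.0224).

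More SNL1, SNL2, SNL3 and SNL4 transcript in mutant replicate 3 than in replicates 1 and 2 may come from wild-type RNA or plants mixed into that sample. SNL2 and SNL3 regained a mean of 5.85% of the wild-type level in replicate 3 (SNL1 15.1%, SNL4 12.2%, SNL5 4.35%), and 9 other genes under 10% of wild type in replicates 1 and 2 regained a median of 6.79% (bootstrap interval 1.16 to 15.7, single genes −0.284 to 25.3%, 323 reads in all against 135.4 expected with no wild-type share and 259.8 with 5.85%), which by the test as first set would favour mixing. Controls added after that result, with another mutant replicate held out in the same way, gave medians of 1.36% (7 genes, replicate 1, −7.05 to 327%) and −1.56% (5 genes, replicate 2, −8.56 to −0.929%). The lower limit of 1.16 is under 1.36, and most of the 9 genes had unsteady wild-type levels (0.877 to 45.5 CPM for AT1G05675, 2.49 to 39.2 for LOX4) apart from AT1G43590 and AT3G47010 (16.0 to 16.5 and 11.7 to 13.7 CPM), which regained 1.16% and −0.284%, so the test leaves mixing open. The transcriptome of replicate 3 as a whole lay nearer to wild type: over 1544 genes called at 2-fold or more without it, a median of 25.9% of the log2 change was missing (24.2 to 28), against 8.03% for replicate 1 and −5.08% for replicate 2, while mixes at the SNL2 and SNL3, SNL4 and SNL1 shares would give 4.25, 9.02 and 11.2%, each too little to account for it alone, and no biological explanation was tested.

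The genes changed at least 4-fold could lie on segments around the SNL loci carried over from the parental mutant lines. Of 197 such genes other than the SNL genes, after 1 without a place in the gene order was left out, 6 (3.05%, exact 95% interval 1.13 to 6.51) lay within 100 annotated genes of the 5 loci, the same share as of all tested genes. This argues against carried-over segments within that window as the source of most of the 197. Longer segments would reach past the window and were not tested. The 6 were AT1G23850, AT1G24140, GolS4, MPL1 and the neighbouring MADS-box genes AT1G59920 and AT1G59930, which lie 3 and 4 genes from SNL5 and rose by 3.38 and 3.29 on the log2 scale. A local effect on that pair stays open and was not tested.

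GC content or gene length bias could make genes pass the threshold. Of 6811 called genes, 91.45% stayed called without the trend of the log2 fold change on both, and all 6229 of these kept their sign, which argues against this bias as the whole cause. The 6 libraries allow 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 3587 and 3224 genes, and the highest of the other splits gave 0 at the same limit and 757 at an unadjusted p below 0.05 (edgeR), against 9085, so 1 split of 10 gave as many higher genes and 1 as many lower genes. Each other split puts both genotypes in both groups, so the genotype difference widens the spread within its groups. These splits therefore do not show what chance alone would give. For gene lists past the camera threshold the real split gave 0, the highest of the others gave 6, and 10 of 10 gave at least as many, which any count would against 0. For the 10 splits the camera p of flowering promoters was as small as the real 0.735 in 8 (smallest of the others 0.0208), and that of flowering repressors as small as the real 0.798 in 8 (smallest of the others 0.242).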
